A study of Homo sapiens with 6 samples.

How the data were processed

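The series holds 6 RNA-seq libraries of the ovarian clear cell carcinoma line TOV21G, in 3 groups of 2: NC, siGYS1 and sip53. NC is read here as the control siRNA, and siGYS1 and sip53 as the knockdowns their names give. This reading comes from the sample titles and the column names of the deposited table, since the labels spell out neither the control nor the siRNA sequences. The label of siGYS1 was checked against the level of GYS1. Whether the replicates were separate cultures, the time after transfection and the sequencing instrument are not given in the sources used here, so every p-value measures only the spread between these libraries. The labels' protocol describes poly(A) selection after a TRIzol-like extraction in general terms.

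The deposited table has 16910 gene rows with human Ensembl identifiers and gives 4 values per library. Per the file headers these are FPKM, TPM, a read count and a normalized read count. The read counts of the authors are expected counts, not normalized, as 16.8% to 18.1% of the deposited values per library are not whole numbers (tolerance 1e-09). The authors' TPM sum to 1000000 in each library. The normalized read count of the deposited table is a normalized signal: it equals the read count, rounded up, times 1 constant per library between 0.944 and 1.033. The submitters' processing notes list FastQC, Trimmomatic, cutadapt, STAR, HISAT2, TopHat, HTSeq, featureCounts, Salmon, DESeq2 and edgeR without versions, roles or order. Which of them made the table is not given in the sources used here. The notes also name the mouse build mm10, although the identifiers are human and 16830 of the 16910 rows are in the human GENCODE 29 annotation. The authors' group means were not used.

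The expected counts were rounded to whole numbers for the fits. The read counts of a library sum to between 17425000 and 18097337, and mitochondrially encoded transcripts take 4.81% to 6.0% of each sum. Counts were fitted in edgeR 4.0.16 (R 4.3.3) with filterByExpr at its default minimum count of 10, TMM factors, estimateDisp, glmQLFit and glmQLFTest. All 6 libraries were in 1 fit with group as the sole term, which leaves 3 residual degrees of freedom. The filter removed 3675 genes and left 13235. The common dispersion was 0.0064 and the prior degrees of freedom 6.67. A gene counts as changed at a Benjamini-Hochberg adjusted p below 0.05, with no minimum fold change. All gene p-values below are such adjusted edgeR quasi-likelihood values, and all log2 fold changes are edgeR estimates given with a standard error (SE), the absolute log2 fold change divided by the square root of the F statistic. FPKM are given as the mean and SD of the 2 libraries of a group.

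The comparisons, tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined. The comparisons are siGYS1 against NC, sip53 against NC, siGYS1 against sip53, and the genes changed in both knockdowns. Gene lists covered p53 targets, glycogen metabolism without GYS1, glycolysis and lactate export, the pentose phosphate pathway, nuclear-encoded oxidative phosphorylation, fatty acid synthesis, cholesterol synthesis, DNA replication, mitosis, apoptosis regulators, the unfolded protein and integrated stress response, hypoxia, NF-kB and cytokine genes, interferon-stimulated genes, immediate early genes, epithelial-mesenchymal and matrix genes, autophagy and lysosome genes, NRF2 and redox genes, ribosomal proteins, clear cell carcinoma markers, epithelial, fibroblast, leukocyte and endothelial markers, mitochondrially encoded transcripts and replication-dependent histones. Of these 26 lists, 25 had at least 4 tested members and were tested with limma camera (limma 3.58.1) on log2 CPM (prior count 2), with its preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 25 lists. The same test with a correlation estimated from the residuals, and limma fry, were run beside it.

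Named genes follow a rule. It takes GYS1; the 6 largest rises and 6 largest falls of each comparison against NC among changed protein-coding genes with a mean FPKM of at least 1 over the 6 libraries and no overlap between both groups; and the 4 largest each way of siGYS1 against sip53. It also takes up to 3 members per list with the largest absolute change among those that passed, or else the member with the smallest p. Among genes changed the same way in both knockdowns it takes the 4 each way with the largest value of the smaller change. Some genes that the rule takes are not reported here. Genes named outside this rule are said to be chosen after their values were seen.

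The overlap of both knockdowns was set against 50 simulations in which no group differs and both comparisons share the control libraries. The calling procedure was tested on simulated data with the dispersion of each gene estimated from these libraries. That dispersion was the same in every group, and noise was drawn separately for each gene. The larger spread between the siGYS1 replicates and trends shared by many genes of a library were not simulated. The test therefore cannot show how many false calls they make. Of 100 genes planted at 1.5-fold, 64 were recovered for siGYS1 and 68 for sip53; at 2-fold these were 84 and 88. Of the genes with no planted change, 8 and 11 were called, in fits of 12993 and 13002 genes that include the planted ones. Replicates with the same number were checked for pairing by correlating their deviations from the group means; the numbers were not treated as pairs.

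Alternatives were a fit of only the groups compared, a replicate block, each library left out in turn, no gene filter, a mean CPM of at least 2, DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma on log2(FPKM + 1), a fold minimum and other adjusted p thresholds. A pair of alternatives was added after seeing the data: offsets that correct each library for a trend with exon length (lowess, span 0.3), and a test without genes whose 3' UTR holds the words described next. Gene coordinates and lengths are from GENCODE 29.

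A search for siRNA seed matches, also added after the first fits, compared log2 fold changes of genes with and without each 7-base word in the 3' UTR, adjusted for 3' UTR length and GC content, over 15903 words found in at least 100 genes. It used 11725 genes with an annotated 3' UTR of at least 50 bases and a mean log2 CPM of at least 1, with fold changes limited to 3 on the log2 scale, and 100 permutations of the fold changes. When a shift of -0.15 was planted for 10 words in permuted data, all 10 came out as the lowest word. These words were drawn from those held by many genes, so the recovery of rarer words was not tested. The length correction was tested on simulated data as well: it brought the correlation with length from 0.26 to 0 and recovered 169 of 200 planted genes, against 167 without it. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The list of leukocyte markers, with 3 tested members, was described but not tested.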

Results

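The series asks what GYS1, the muscle-type glycogen synthase, does in the ovarian clear cell carcinoma line TOV21G, and its title pairs GYS1 with p53. The siRNA against GYS1 left its target transcript at a small share of the control level. GYS1 was at 27.9 ± 0.926 FPKM (mean ± SD of 2 libraries) with NC and 1.68 ± 0.014 with siGYS1, which is 6.29% of NC by the edgeR fit (log2 fold change -3.99, SE 0.11, adjusted p = 1.28e-07). With sip53, GYS1 did not pass the test (log2 fold change 0.22, SE 0.08, adjusted p = 0.056). This value passes without siGYS1 replicate 1 (adjusted p = 0.0349) or siGYS1 replicate 2 (adjusted p = 0.0208), at 0.22 and 0.24, and in 6 other settings.

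**Figure D1:**
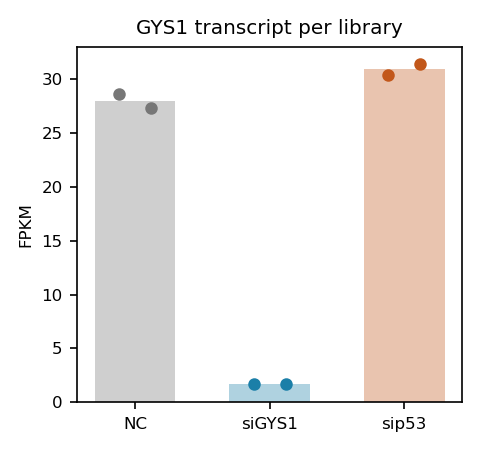
FPKM of GYS1 in each of the 6 libraries (points), with the group mean as a bar. GYS1 lies at 1.69 and 1.67 FPKM in the siGYS1 libraries and above 25 FPKM in the other groups.

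With siGYS1, the largest rises against NC included the cytokine gene CSF2 (9.27-fold, log2 3.21, SE 0.47, adjusted p = 0.00199), the lymphocyte activation marker CD69 (6.40-fold, log2 2.68, SE 0.26, adjusted p = 0.000213) and IL6R, the interleukin-6 receptor (4.98-fold, log2 2.32, SE 0.14, adjusted p = 3.42e-05). CA9, a carbonic anhydrase induced by hypoxia, rose 5.59-fold from 0.285 ± 0.021 to 1.55 ± 0.29 FPKM, and ANKRD1, a target of YAP, rose 5.53-fold from 0.22 to 1.2 FPKM. TMEM265 rose 11.6-fold (log2 3.54, SE 0.64) from a level near 0; without NC replicate 2 its log2 fold change is 8.33, because the other NC library has 0 reads of it. The largest falls were in the chemokine receptor gene CCR10 (log2 -2.62, SE 0.15, from 19.1 to 2.63 FPKM), PNPLA6 (-2.21, SE 0.09), which encodes a lysophospholipase, LCMT1 (-2.03, SE 0.16), which encodes a methyltransferase of protein phosphatase 2A, AGR2 (-2.01, SE 0.30), BIN1 (-1.89, SE 0.11) and the immediate early transcription factor gene EGR1 (-1.89, SE 0.13). Their adjusted p-values ran from 5.25e-06 for PNPLA6 to 0.00231 for AGR2. Of these falling genes BIN1 holds in its 3' UTR the 7-base word GTCCTCT, which goes with the falls under siGYS1, and of the falling genes named next so does SHMT2. So do SLC2A1 and ATF3, which rose. Of the rising ones, IL6R, SLC2A3, PPP1R3B, INSIG1, RPA2, ANLN, MAP1LC3B and CEACAM1 hold TGTTTAC, a word that goes with rises in both knockdowns, or GTTTACA, which goes with rises under siGYS1, and so do the falling H6PD and SDHC. Values after gene names are log2 fold changes against NC.

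Among metabolic genes, 12 of 18 hypoxia genes rose with siGYS1 and 0 fell, with CA9 (log2 2.48, SE 0.38) foremost (limma camera adjusted p = 5.6e-07; adjusted p = 0.39 with an estimated correlation). Of 24 genes of glycolysis and lactate export, 11 rose, such as the glucose transporter genes SLC2A3 (1.63, SE 0.13) and SLC2A1 (0.97, SE 0.08), and 1 fell, the phosphofructokinase gene PFKM (-0.97, SE 0.08; camera adjusted p = 0.00053, adjusted p = 0.44 with an estimated correlation). Without NC replicate 2, 7 of them rose. Of 37 nuclear-encoded genes of oxidative phosphorylation 6 fell and 0 rose, among them SDHC (-0.52, SE 0.08), a subunit of succinate dehydrogenase; the list was called lower (camera adjusted p = 8.4e-06; adjusted p = 0.67 with an estimated correlation). The median of that list depends on single libraries: it is -0.23 in the full fit, -0.15 without NC replicate 2, -0.09 without siGYS1 replicate 1 and -0.35 without siGYS1 replicate 2. The count of 6 falls is 1 without NC replicate 2, 2 without either sip53 library, 3 without siGYS1 replicate 1 and 26 without siGYS1 replicate 2. Relative to the mean of the 6 libraries, log2 CPM in siGYS1 replicate 1 rose with exon length (Spearman rho 0.41 across genes above log2 CPM 2). In NC replicate 2 it fell with exon length (-0.29), against -0.08 in siGYS1 replicate 2 and 0.04 in NC replicate 1. The fold changes of siGYS1 against NC follow length too (0.27). With length-corrected offsets the oxidative phosphorylation list was still called lower by camera with the preset correlation. The rest of glycogen metabolism was not called (2 up and 2 down of 24, camera adjusted p = 0.96). PPP1R3B, a glycogen-targeting subunit of protein phosphatase 1, was at 0.78 (SE 0.11). In the pentose phosphate pathway TKT rose (0.51, SE 0.09) and H6PD fell (-0.57, SE 0.10) among 10 genes, with no call for the list (adjusted p = 0.99). Fatty acid synthesis (3 up, 1 down of 14, adjusted p = 0.36) holds INSIG1, a sterol-regulated gene that rose by 1.72 (SE 0.09). Cholesterol synthesis (2 up, 5 down of 21, adjusted p = 0.16) holds a fall in TM7SF2 (-0.96, SE 0.11).

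Of 39 p53 target genes, 17 rose with siGYS1 and 1 fell, with BTG2 (log2 1.32, SE 0.10), CCNG1 (0.75, SE 0.08) and FBXW7 (0.65, SE 0.10) as the largest; the list was called higher (camera adjusted p = 4.5e-05; adjusted p = 0.3 with an estimated correlation). The 17 rises are 6 without NC replicate 2, 8 without NC replicate 1 and 9 without either sip53 library. Mitosis genes were called higher (7 up, 0 down of 34, adjusted p = 0.00053; adjusted p = 0.6 with an estimated correlation). CENPE was at 1.61 (SE 0.20) and ANLN at 0.69 (SE 0.11). The 7 rises are 2 without NC replicate 2 or either sip53 library, 4 without NC replicate 1 or siGYS1 replicate 1, and 11 without siGYS1 replicate 2. DNA replication genes were not (2 up, 1 down of 34, adjusted p = 0.64), although RPA2 rose by 0.53 (SE 0.10). Apoptosis regulators were called higher (11 up, 1 down of 22, adjusted p = 0.00068; adjusted p = 0.3 with an estimated correlation), and the BH3-only genes HRK (2.15, SE 0.15) and BMF (0.92, SE 0.10) rose. That call is lost without genes that hold any seed word (camera adjusted p = 0.6), a setting that leaves 6661 of 13235 tested genes. It cannot tell a seed effect from the loss of list members. HRK and BMF hold only AGAGAAA or AAGAGAA, words that go with the falls under sip53. Without NC replicate 2 the list median is 0.4, against 0.36 in the full fit.

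Redox, autophagy and inflammatory genes rose as lists with siGYS1. The NRF2 and redox list was called higher (8 up, 1 down of 20, camera adjusted p = 0.00054; adjusted p = 0.56 with an estimated correlation), led by HMOX1 (1.38, SE 0.12) and TXNRD1 (1.27, SE 0.10), with 5 rises without NC replicate 2 or either sip53 library. So were autophagy and lysosome genes (6 up, 0 down of 23, adjusted p = 0.00062; adjusted p = 0.39 with an estimated correlation). The autophagy receptor SQSTM1 was at 1.03 (SE 0.09) and MAP1LC3B at 0.56 (SE 0.09), and 3 genes of the list rose without NC replicate 2. Cytokine and NF-kB genes were called higher (7 up, 3 down of 22, adjusted p = 0.0031; adjusted p = 0.37 with an estimated correlation). CCL20 was at 1.31 (SE 0.08, from 194 to 456 FPKM) and CXCL8 at 1.08 (SE 0.08). Interferon-stimulated genes were too (8 up, 1 down of 29, adjusted p = 0.0032; adjusted p = 0.3 with an estimated correlation). OASL was at 2.18 (SE 0.37) and MX1 at 1.34 (SE 0.15). The unfolded protein and integrated stress response went both ways (4 up, 9 down of 24, adjusted p = 0.16). ATF3 was at 1.10 (SE 0.21) and the serine pathway gene SHMT2 at -0.68 (SE 0.12). Immediate early genes did as well (7 up, 5 down of 17, adjusted p = 0.45). KLF6 was at 1.17 (SE 0.11) against the fall of EGR1.

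Epithelial markers were called lower with siGYS1 (0 up, 5 down of 11, camera adjusted p = 0.018; adjusted p = 0.61 with an estimated correlation), a call lost without siGYS1 replicate 1 (adjusted p = 0.11). Without NC replicate 2 the list keeps its call (adjusted p = 0.015, median -0.36 against -0.37), but 0 of its genes pass. KRT18 fell by 0.55 (SE 0.10), a call lost without NC replicate 2 (-0.48, adjusted p = 0.0555). Epithelial-mesenchymal and matrix genes were called higher (9 up, 3 down of 26, adjusted p = 0.04; adjusted p = 0.39 with an estimated correlation), with THBS1 against the trend (-0.99, SE 0.10). That call is lost without NC replicate 2 (adjusted p = 0.056), siGYS1 replicate 1 (adjusted p = 0.073, median 0.19 in place of 0.31) or siGYS1 replicate 2 (adjusted p = 0.055), and in 3 other settings, and 4 genes rose without NC replicate 2. Clear cell carcinoma markers (1 up, 1 down of 13, adjusted p = 0.9) hold CEACAM1 (0.82, SE 0.16; 0.72 and adjusted p = 0.074 without NC replicate 2). None of the 6 fibroblast or 4 endothelial markers and none of the 39 ribosomal protein genes passed in edgeR (camera adjusted p = 0.9, 0.79 and 0.16); the smallest p in each belonged to MFAP5 (1.61, adjusted p = 0.122), ESAM (-0.50, adjusted p = 0.475) and RPL10A (-0.21, adjusted p = 0.2), of which MFAP5 passed with limma on FPKM (adjusted p = 0.00637). RPL10A also passed without siGYS1 replicate 2 (-0.30, adjusted p = 0.0491). Of 3 tested leukocyte markers, CORO1A passed (-0.71, SE 0.14; -0.63 and adjusted p = 0.0665 without NC replicate 2). Of 6 histone genes, H2AC6 passed (-0.57, list adjusted p = 0.39), and not without NC replicate 2 (-0.42, adjusted p = 0.185) or siGYS1 replicate 1 (-0.49, adjusted p = 0.0546). Of 13 mitochondrially encoded transcripts, MT-CO2 passed (-0.34, adjusted p = 0.047, list adjusted p = 0.79), a call that 9 alternatives end, such as leaving out NC replicate 2 (-0.21, adjusted p = 0.304), siGYS1 replicate 1 (adjusted p = 0.13), sip53 replicate 1 (adjusted p = 0.0898) or sip53 replicate 2 (adjusted p = 0.0882).

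In all, 2602 of 13235 tested genes changed with siGYS1 (19.7%), 1379 up and 1223 down, and 142 and 173 of them by at least 2-fold. Of 25 gene lists 12 were called, 10 higher and 2 lower. Adjusted over the list alone, the counts up and down were 22 and 3 for p53 targets, 13 and 2 for apoptosis regulators, 8 and 3 for cytokine genes, 8 and 2 for interferon-stimulated genes, 11 and 4 for matrix genes, 9 and 1 for redox genes, 8 and 6 for immediate early genes, 4 and 10 for the stress response, 4 and 1 for fatty acid synthesis, 2 and 1 for clear cell markers and 0 and 0 for mitochondrial transcripts, and the same as above for the other lists. With an estimated correlation camera called 0 of the 25 lists (3 at an unadjusted p below 0.05), while limma fry, which asks only whether a list moves one way, called 11. The count of genes is 926 without NC replicate 2, 1696 without NC replicate 1, 1550 and 1571 without sip53 replicates 1 and 2, and 4260 without siGYS1 replicate 2. It is 1577 when only both compared groups are fitted, 642 up and 1172 down with limma on FPKM, and 1398 up and 799 down with the DESeq2 Wald test.

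With sip53, the largest rises against NC were in the collagenase gene MMP1 (119-fold, log2 6.89, SE 0.30, from 0.085 to 9.64 FPKM) and CSF2 (116-fold, log2 6.86, SE 0.30, from 0.275 to 31.5 FPKM). TMEM265 (log2 5.46, SE 0.51; 10.26 without NC replicate 2), the cardiac actin gene ACTC1 (5.16, SE 0.29), G0S2 (4.90, SE 0.27), an inhibitor of triglyceride lipase, and the cytokine gene TNFSF15 (4.64, SE 0.21) followed. The largest falls included SLC17A8, a vesicular glutamate transporter gene (-6.67, SE 0.26, from 6.83 to 0.06 FPKM), the defensin gene DEFB1 (-4.31, SE 0.35), the Wnt inhibitor gene DKK1 (-3.72, SE 0.10, from 104 to 7.39 FPKM), MPZL1 (-3.59, SE 0.11) and MBNL3 (-3.58, SE 0.23). The adjusted p-values of these genes ran from 5.02e-08 for DKK1 to 2.68e-05 for TMEM265. The 3' UTRs of SLC17A8, DKK1, MPZL1 and MBNL3 hold the word AGAGAAA or AAGAGAA, which goes with the falls under sip53, and so do those of MDM2, E2F2, GINS2, RPIA, ACACB, EBP, THBS1, SPP1, COL1A2 and CORO1A among the falling genes named next. The same words stand in G0S2, TNFSF15, TNFRSF10B, SLC2A3, HK2, CXCL8, IFI44, TXNRD1, SQSTM1, SLC7A11, HRK, DUSP1, ITGA5, DCN and H2BC21, which rose with sip53. ACTC1 and TNFSF15, and further on TNFRSF10B, SLC2A3, INSIG1, SLC7A11, IL1A and ITGA5, hold GTTTACA or TGTTTAC, and so do the falling MBNL3, MDM2 and RPIA. On log2(FPKM + 1), folds of genes near 0 FPKM are smaller by construction, such as 3.28 for MMP1 and -2.88 for SLC17A8.

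The fixed list of p53 target genes split with sip53: 14 of 39 fell, among them MDM2 (log2 -1.58, SE 0.10), the feedback inhibitor of p53, and FDXR (-1.36, SE 0.12), and 9 rose, among them the death receptor gene TNFRSF10B (1.60, SE 0.08). The list was not called (camera adjusted p = 0.31). Of the 17 members that rose with siGYS1, 7 also rose with sip53, 3 fell and 7 did not pass. BTG2 (0.36) and CCNG1 (0.63) rose in both, while FBXW7 was at -0.11 and did not pass with sip53. Of the 14 members that fell with sip53, 3 rose with siGYS1 and 11 did not pass, MDM2 and FDXR among these 11. DNA replication genes fell (27 down, 2 up of 34, camera adjusted p = 8.7e-09; adjusted p = 0.35 with an estimated correlation). E2F2 was at -1.54 (SE 0.12), MCM6 at -1.48 (SE 0.10) and GINS2 at -1.36 (SE 0.13). Mitosis genes fell too (31 down, 1 up of 34, adjusted p = 8.7e-09; adjusted p = 0.34 with an estimated correlation). HMMR was at -2.01 (SE 0.11), CENPF at -1.57 (SE 0.16) and the proliferation marker MKI67 at -1.54 (SE 0.14). Replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, were listed as a sign of RNA quality. The list holds 30 symbols, an older and a newer one for each gene. Of its genes, 11 were in the deposited table and 6 could be tested. They rose with sip53 beside the falls above and the changes in the next paragraphs (median 1.32; 5 up, 0 down of 6, adjusted p = 0.012; adjusted p = 0.35 with an estimated correlation). H2BC4 was at 2.04 (SE 0.21) and H2BC21 at 1.90 (SE 0.22). The other list kept for RNA quality, mitochondrially encoded transcripts, was not called (camera adjusted p = 0.62). Whether the histone rise reflects RNA quality was not tested.

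**Figure D2:**
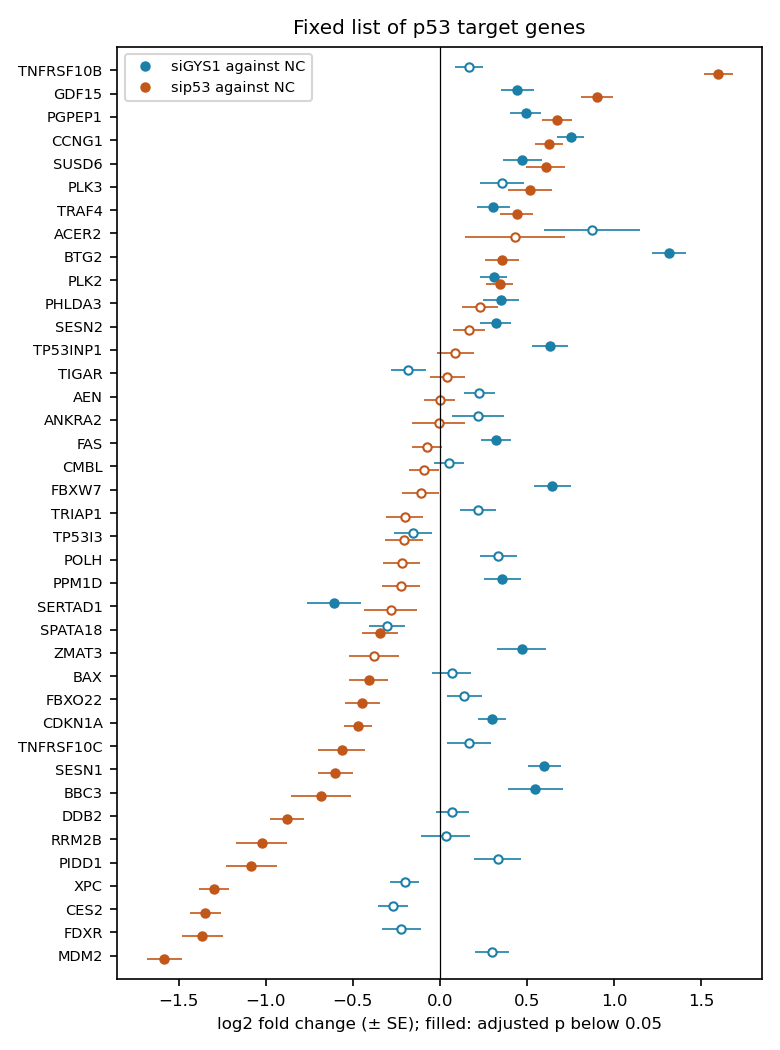
Log2 fold change against NC (x axis, with SE bars) of each tested p53 target gene (y axis), for siGYS1 and sip53; filled points passed the test. With siGYS1 17 genes rose and 1 fell, and with sip53 9 rose and 14 fell.

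Glycolysis and lactate export rose with sip53 (18 up, 0 down of 24, camera adjusted p = 2.8e-09, and 0.22 with an estimated correlation), beside the histone genes listed for RNA quality (median 1.32). SLC2A3 was at 2.94 (SE 0.13), SLC2A1 at 2.42 (SE 0.09, from 57.9 to 284 FPKM) and the hexokinase gene HK2 at 1.89 (SE 0.11). Hypoxia genes rose as well (17 up, 0 down of 18, adjusted p = 9.4e-11; adjusted p = 0.22 with an estimated correlation). CA9 was at 3.69 (SE 0.34), NDRG1 at 3.05 (SE 0.11) and ANGPTL4 at 2.81 (SE 0.12). Glycogen metabolism was called higher (11 up, 1 down of 24, adjusted p = 0.044; adjusted p = 0.33 with an estimated correlation). The targeting subunit gene PPP1R3C was at 1.88 (SE 0.33). The list's call is lost in 11 of 14 settings, among them without NC replicate 1 (adjusted p = 0.075), NC replicate 2 (0.062), siGYS1 replicate 1 (0.071), siGYS1 replicate 2 (0.053) or sip53 replicate 1 (0.084), and 7 genes rose without NC replicate 2 or sip53 replicate 1. The pentose phosphate pathway went both ways (4 up, 4 down of 10, adjusted p = 0.78). TKT was at 0.82 (SE 0.09) and RPIA at -1.14 (SE 0.09). Split as well was fatty acid synthesis (3 up, 5 down of 14, adjusted p = 0.43). INSIG1 was at 2.02 (SE 0.09) and ACACB at -2.07 (SE 0.22). Cholesterol synthesis (4 up, 10 down of 21, adjusted p = 0.094) holds the fall of EBP (-0.99, SE 0.10). In nuclear-encoded oxidative phosphorylation 2 of 37 genes fell and 0 rose (adjusted p = 0.78), with SDHA at -0.63 (SE 0.09).

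Inflammatory genes rose with sip53, again beside the histone genes (median 1.32): 16 of 22 NF-kB and cytokine genes were higher and 2 lower (camera adjusted p = 7.9e-06; adjusted p = 0.22 with an estimated correlation). The neutrophil chemokine gene CXCL8 was at 3.22 (SE 0.09, from 282 to 2438 FPKM) and IL1A at 3.04 (SE 0.27). Interferon-stimulated genes rose (23 up, 2 down of 29, adjusted p = 1.8e-07; adjusted p = 0.21 with an estimated correlation). OASL was at 3.53 (SE 0.32) and IFI44 at 4.14 (SE 0.59), the latter still below 1 FPKM. Redox genes rose (11 up, 3 down of 20, adjusted p = 0.0038; adjusted p = 0.41 with an estimated correlation). HMOX1 was at 3.48 (SE 0.13, from 28.7 to 293 FPKM) and TXNRD1 at 1.90 (SE 0.10). Autophagy and lysosome genes rose (18 up, 3 down of 23, adjusted p = 4e-05; adjusted p = 0.28 with an estimated correlation). The protease gene CTSD was at 1.65 (SE 0.10) and SQSTM1 at 1.62 (SE 0.09). The stress response rose (13 up, 5 down of 24, adjusted p = 0.0097; adjusted p = 0.41 with an estimated correlation). The cystine transporter gene SLC7A11 was at 1.83 (SE 0.16) and CEBPB at 1.59 (SE 0.11). Apoptosis regulators rose (12 up, 4 down of 22, adjusted p = 0.0097; adjusted p = 0.22 with an estimated correlation), led by the anti-apoptotic BCL2A1 at 3.36 (SE 0.29) and the pro-apoptotic HRK at 2.14 (SE 0.15). Without genes that hold any seed word the call is lost (camera adjusted p = 0.35), which again cannot tell a seed effect from the loss of list members. Immediate early genes went both ways (9 up, 6 down of 17, adjusted p = 0.13). DUSP1 was at 1.81 (SE 0.12) and EGR1 at -2.22 (SE 0.14).

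Epithelial-mesenchymal and matrix genes rose with sip53 (16 up, 4 down of 26, camera adjusted p = 0.0014; adjusted p = 0.22 with an estimated correlation; median 0.46, and 0.72 without NC replicate 1). The integrin gene ITGA5 was at 2.84 (SE 0.09) against THBS1 at -3.31 (SE 0.11). Epithelial markers went both ways (2 up, 4 down of 11, adjusted p = 0.64). CLDN4 was at 2.15 (SE 0.14) and EPCAM at -1.54 (SE 0.20). Clear cell carcinoma markers did too (6 up, 3 down of 13, adjusted p = 0.53). DPP4 was at 3.76 (SE 0.25) and SPP1, which encodes osteopontin, at -2.30 (SE 0.10, from 3487 to 669 FPKM). Of 6 fibroblast markers 2 rose and 4 fell (adjusted p = 0.44): COL1A2 was at -0.88 (SE 0.08) and DCN at 4.23 (SE 0.40) on counts, but DCN was not called on FPKM (0.56, adjusted p = 0.517 with limma). Of 4 endothelial markers 3 rose (adjusted p = 0.052), the most abundant being TIE1 at 1.37 (SE 0.11, from 3.38 to 8.04 FPKM). Of 3 leukocyte markers CD68 rose (0.81, SE 0.15) and CORO1A fell (-0.54, SE 0.14; lost without NC replicate 2, sip53 replicate 1 or sip53 replicate 2, adjusted p = 0.0722, 0.0689 and 0.0528). Of 13 mitochondrially encoded transcripts 4 rose and 3 fell (adjusted p = 0.62). MT-CO3 was at -0.62 (SE 0.09). Of 39 ribosomal protein genes 5 rose and 3 fell (adjusted p = 0.099), and the rises are 0 without NC replicate 1 or either sip53 library, 8 without NC replicate 2, and 10 and 11 without siGYS1 replicates 1 and 2.

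**Figure D3:**
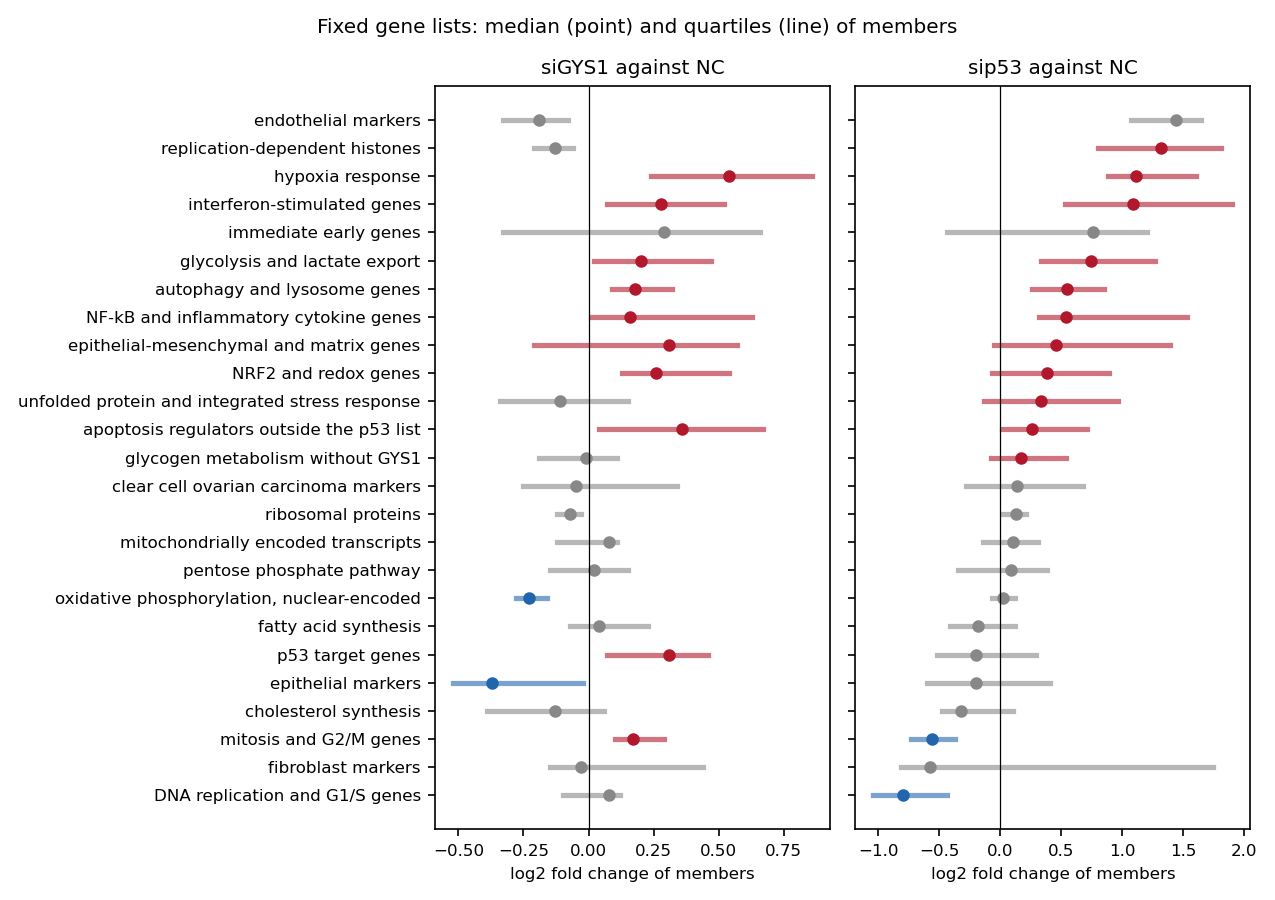
Median (point) and quartiles (line) of the log2 fold changes of each tested list's members, for siGYS1 and sip53 against NC on separate scales; red lists were called higher and blue lists lower by camera, grey ones not called. Hypoxia genes have medians of 0.54 and 1.11, and mitosis genes of 0.17 and -0.56.

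In all, 6605 of 13235 genes changed with sip53 (49.9%), 3103 up and 3502 down, and 721 and 930 of them by at least 2-fold; 13 of 25 lists were called, 11 higher and 2 lower. Adjusted over the list alone, the counts up and down were 9 and 15 for p53 targets, 20 and 0 for glycolysis, 3 and 6 for fatty acid synthesis, 4 and 11 for cholesterol synthesis, 2 and 28 for DNA replication, 1 and 32 for mitosis, 15 and 5 for the stress response, 17 and 2 for cytokine genes, 24 and 3 for interferon-stimulated genes, 0 and 0 for ribosomal proteins, 6 and 4 for clear cell markers and 4 and 4 for epithelial markers, and the same as above for the other lists. Camera with an estimated correlation called 0 lists (5 at an unadjusted p below 0.05) and fry 18. The count of genes is 4271 without sip53 replicate 1. With limma on FPKM it is 1966 up and 3597 down, and the median of all genes is -0.103 in place of -0.029.

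Set against each other, the largest differences between siGYS1 and sip53, beside GYS1 (-4.21, SE 0.11), included SLC17A8 (log2 5.30 higher with siGYS1, SE 0.29), MPZL1 (3.51, SE 0.11) and MBNL3 (3.30, SE 0.23). On the other side, MMP1 (-6.00, SE 0.28), VGF (-4.84, SE 0.11), a neuropeptide precursor gene, TNFSF15 (-4.56, SE 0.21) and DPP4 (-4.51, SE 0.28) were lower with siGYS1. The adjusted p-values of SLC17A8 and the 6 genes after it ran from 3.23e-08 for VGF to 6.48e-06 for MBNL3. Mitosis genes were higher with siGYS1 (32 up, 0 down of 34, camera adjusted p = 2e-13; adjusted p = 0.29 with an estimated correlation), such as HMMR (2.12, SE 0.11), and so were DNA replication genes (27 up, 1 down of 34, adjusted p = 4.9e-11; adjusted p = 0.29 with an estimated correlation), such as CLSPN (1.26, SE 0.12). The p53 target list was higher with siGYS1 (21 up, 2 down of 39, adjusted p = 0.00016; adjusted p = 0.21 with an estimated correlation). MDM2 was at 1.88 (SE 0.10) and PIDD1 at 1.42 (SE 0.15) against TNFRSF10B at -1.43 (SE 0.08).

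Glycolysis was lower with siGYS1 than with sip53 (1 up, 18 down of 24, camera adjusted p = 7.1e-08; adjusted p = 0.29 with an estimated correlation), as with ENO2 at -1.37 (SE 0.09). Hypoxia genes were lower (1 up, 16 down of 18, adjusted p = 1.1e-06; adjusted p = 0.29 with an estimated correlation), as with ANGPTL4 at -2.14 (SE 0.12), with 10 down without sip53 replicate 1. Interferon-stimulated genes were lower too (2 up, 21 down of 29, adjusted p = 9.6e-06; adjusted p = 0.21 with an estimated correlation), as with MX1 at -1.83 (SE 0.12). Cytokine genes (2 up, 13 down of 22, adjusted p = 0.0012; adjusted p = 0.29 with an estimated correlation) were also lower, as with CXCL8 at -2.14 (SE 0.08). The stress response (2 up, 15 down of 24, camera adjusted p = 0.00023, and 0.29 with an estimated correlation) was lower, as with TRIB3 at -1.19 (SE 0.09). The 3' UTR of TRIB3 holds GTCCTCT, a sip53 word and GTTTACA or TGTTTAC. Autophagy and lysosome genes (2 up, 14 down of 23, adjusted p = 0.002; adjusted p = 0.29 with an estimated correlation) followed, as with CTSL at -0.72 (SE 0.09), with 8 down without sip53 replicate 1. All 6 tested histone genes, listed as a sign of RNA quality, were lower (median -1.46, camera adjusted p = 0.0011, and 0.29 with an estimated correlation), as with H2BC4 at -2.25 (SE 0.21). They stand beside these lists and the mitosis, DNA replication and p53 target lists of the paragraph before.

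The list of nuclear-encoded oxidative phosphorylation was called lower with siGYS1 than with sip53 (1 up, 12 down of 37, camera adjusted p = 0.0011; adjusted p = 0.65 with an estimated correlation), as with SDHC at -0.63 (SE 0.08). Its median of -0.21 is -0.08 without siGYS1 replicate 1 (adjusted p = 0.095, call lost) and -0.34 without siGYS1 replicate 2. The 12 lower genes are 5 and 28 without these libraries, and 3 without either sip53 library. Ribosomal proteins were called lower (1 up, 7 down of 39, adjusted p = 0.0067; adjusted p = 0.71 with an estimated correlation). Their median of -0.18 is -0.06 without siGYS1 replicate 1 (adjusted p = 0.41, call lost) and -0.32 without siGYS1 replicate 2. The 7 lower genes are 3 and 24 without these libraries, 1 without sip53 replicate 1 and 0 without sip53 replicate 2. Endothelial markers were called lower (0 up, 3 down of 4, adjusted p = 0.021; adjusted p = 0.29 with an estimated correlation), as with TIE1 at -1.34 (SE 0.11), but not with no gene filter (adjusted p = 0.077). Glycogen metabolism was called lower (1 up, 9 down of 24, adjusted p = 0.024; adjusted p = 0.29 with an estimated correlation), as with STBD1 at -0.77 (SE 0.10). That call is lost without siGYS1 replicate 1 (adjusted p = 0.056) or sip53 replicate 1 (adjusted p = 0.066) and in 3 other settings.

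The lists not called between siGYS1 and sip53, each with its camera adjusted p, were the pentose phosphate pathway (1 up, 2 down of 10, 0.52; RPIA at 1.31, SE 0.09), fatty acid synthesis (8 up, 3 down of 14, 0.095; ELOVL5, which holds a sip53 word and GTTTACA or TGTTTAC, at 0.57, SE 0.09), cholesterol synthesis (7 up, 4 down of 21, 0.35; EBP at 0.86, SE 0.10), apoptosis regulators (7 up, 5 down of 22, 0.76; MCL1, which holds GTCCTCT and a sip53 word, at -1.20, SE 0.09) and immediate early genes (3 up, 8 down of 17, 0.18; JUNB at -0.92, SE 0.11). Matrix genes (8 up, 11 down of 26, 0.062; ITGA5 at -2.06, SE 0.09), redox genes (3 up, 7 down of 20, 0.088; HMOX1 at -2.10, SE 0.12), clear cell markers (2 up, 2 down of 13, 0.79; SPP1 at 2.04, SE 0.10), epithelial markers (3 up, 4 down of 11, 0.23; CLDN4 at -1.78, SE 0.13), fibroblast markers (3 up, 1 down of 6, 0.4; COL1A2 at 0.72, SE 0.08) and mitochondrial transcripts (3 up, 2 down of 13, 0.79) were not called either. Of 3 leukocyte markers CD68 passed (-0.54, SE 0.15; -0.47 and adjusted p = 0.102 without sip53 replicate 1, and not called by the DESeq2 Wald test or limma on FPKM).

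In all, 5745 of 13235 genes differed between the knockdowns (43.4%), 2979 higher and 2766 lower with siGYS1, and 14 of 25 lists were called, 3 higher and 11 lower. Adjusted over the list alone, the counts up and down were 22 and 2 for p53 targets, 0 and 6 for oxidative phosphorylation, 8 and 4 for cholesterol synthesis, 7 and 6 for apoptosis regulators, 2 and 15 for autophagy genes, 0 and 5 for ribosomal proteins and 3 and 6 for epithelial markers, and the same as above for the other lists. Camera with an estimated correlation called 0 lists (2 at an unadjusted p below 0.05) and fry 16. The count of genes is 3416 without sip53 replicate 1 and 3485 without sip53 replicate 2.

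Many genes changed the same way against NC in both knockdowns. TMEM265, CSF2, CD69 and CA9 rose most in both: CD69 had a log2 fold change of 2.68 (SE 0.26) with siGYS1 and 4.35 (SE 0.22) with sip53, and CSF2 3.21 and 6.86. AGR2, EGR1, MAJIN and CA14 fell most in both: EGR1 went from 11.5 ± 0.41 FPKM with NC to 2.97 ± 0.509 with siGYS1 and 2.29 ± 0.12 with sip53, and the carbonic anhydrase gene CA14 had -1.73 (SE 0.15) and -1.78 (SE 0.16). MAJIN and CA14 hold the siGYS1 word GTCCTCT and no sip53 word, and the rising CD69 holds a sip53 word. In all, 1843 genes changed in both, 1569 of them in the same direction (893 up, 676 down) and 274 in opposite directions (144 up with siGYS1 and down with sip53, 130 the reverse). Independent calls would give 323.3 genes up in both and 323.6 down in both, and 364.9 and 286.7 in opposite directions. Of the 1569 genes 665 (42.4%) also differed between the knockdowns, 593 of them with the larger change under sip53 and 72 under siGYS1.

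**Figure D4:**
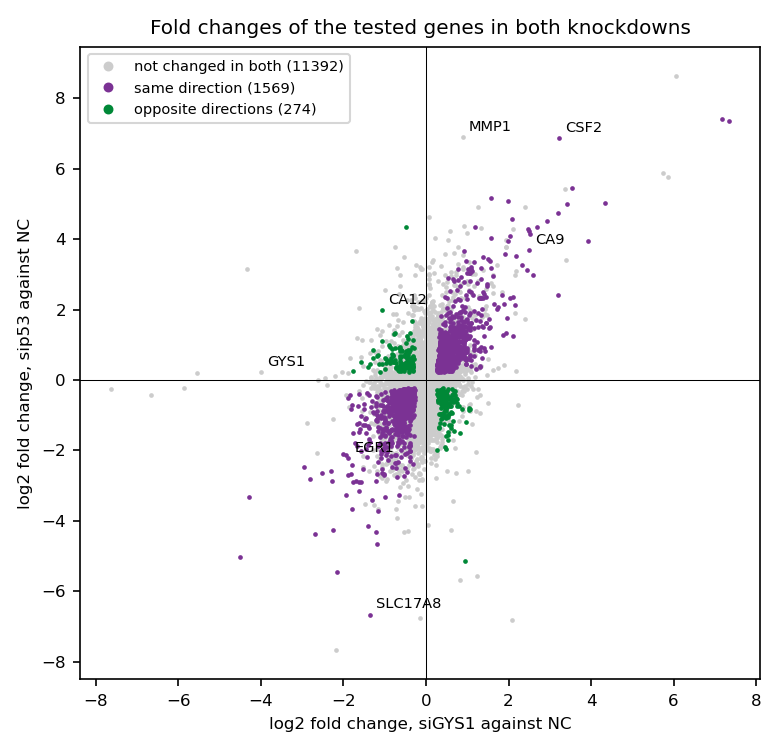
Log2 fold change of each tested gene with sip53 (y axis) against that with siGYS1 (x axis), both against the same NC libraries. Purple points are the 1569 genes changed in the same direction in both and green points the 274 changed in opposite directions.

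Across genes, which are not independent replicates, the fold changes of both knockdowns correlate with Pearson r = 0.506 and Spearman rho = 0.434. Sharing the 2 NC libraries alone produces such a correlation: in 50 simulations with no difference between groups the median r was 0.485 (0.438 to 0.548). The covariance of the fold changes was 0.1912, against a simulated median of 0.0185 and a highest value of 0.0225, and the simulations gave at most 2 genes called the same way in both. Part of the excess of 0.1727 may come from the shared controls, which cannot be split with 2 NC libraries. The count of 1569 is 571 without NC replicate 2, 1000 without NC replicate 1, and 838 and 882 without sip53 replicates 1 and 2. It is 425 up and 679 down with limma on FPKM, and 891 up and 369 down with the DESeq2 Wald test.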

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

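The length-corrected offsets and the tests without seed-word genes were chosen after seeing the data; the other settings were fixed before. With groups of 2 libraries, each setting without a library leaves 1 library in a group, which is assumed to vary like the others. At this depth, of 17425000 to 18097337 reads per library, simulated 1.5-fold changes were found in 64 of 100 genes for siGYS1, so smaller changes can be missed. The rule took named genes mainly for large changes that passed in the full fit. The counts that follow therefore do not describe changed genes at large. The 235 results of named genes other than GYS1 gave 3354 values under the alternatives: 3195 kept direction and side of the threshold, 156 lost the call, 3 gained it and 0 reversed.

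Changed genes numbered 2602 (siGYS1 against NC), 6605 (sip53 against NC), 5745 (siGYS1 against sip53) and 1569 (the same way in both). A log2 fold minimum of 1 leaves 315, 1651, 1280 and 190 by construction, and an adjusted p below 0.01 leaves 1023, 3740 and 617 for siGYS1, the direct comparison and both. Without seed-word genes 6661 genes are tested and 1171, 3293, 2706 and 776 change. A fit of only the groups compared leaves 2 residual degrees of freedom and gives 1577 for siGYS1, 7589 for sip53 and 5485 for the direct comparison. Replicates lay further apart with siGYS1 (median absolute log2 difference 0.161) than with NC (0.115) or sip53 (0.082). The fit of all libraries takes the spread of a gene from all groups together. Its count for siGYS1 against NC therefore also rests on the closer sip53 replicates. Leaving out 1 library gave 926 to 4260, 4271 to 7621, 3416 to 6337 and 571 to 2259 genes; beyond the single lone library, the cause was not tested. The correlation of both knockdowns stayed between 0.442 and 0.593. Libraries with the same replicate number were not treated as pairs: their deviations correlated at 0.28 (NC and siGYS1), -0.02 (NC and sip53) and 0.13 (siGYS1 and sip53), and the labels give no shared batch. A replicate block raises the counts to 4662 for siGYS1 and 2716 for both, and gives GYS1 with sip53 0.22 (adjusted p = 0.0183) and RPL10A with siGYS1 -0.21 (adjusted p = 0.0417).

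Without each library in turn, GYS1 with siGYS1 was -4.02 to -3.96. GYS1 with sip53 was 0.18 to 0.25, called higher without either siGYS1 library. It was also called with a fit of both groups only (0.24, adjusted p = 0.0199), no gene filter (0.24, 0.0446), DESeq2 size factors (0.24, 0.0367), length-corrected offsets (0.23, 0.0197) and without seed-word genes (0.22, 0.0402); the cause was not tested. Lists called numbered 10 to 13, 12 to 14 and 12 to 16 without 1 library, and 0, 0 and 0 in the 3 comparisons with an estimated correlation, which allows for correlated members; at an unadjusted p below 0.05 these camera tests gave 3, 5 and 2 lists, and fry called 11, 18 and 16. Pseudocounts, quantile, TPM and TMM scaling of FPKM and other variance models for FPKM were not run, since they change only a test on FPKM, and DESeq2 gave no list tests.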

Other observations

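The genes in the next paragraph, the shares of lower genes with seed words, the tests on genes changed the same way in both knockdowns except that on every joint rise, and the p53 tests against genes outside the list were chosen after the results were seen; the other tests were written before their results were.

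Among the 274 genes that changed in opposite directions, IL1RAP, the accessory chain of the interleukin-1 receptor, rose with siGYS1 (log2 1.06, SE 0.12) and fell with sip53 (-0.81, SE 0.13). The ubiquitin ligase subunit gene SKP2 had 0.79 (SE 0.11) and -0.73 (SE 0.11), and DDAH1 0.87 (SE 0.09) and -0.82 (SE 0.10). The carbonic anhydrase gene CA12 went the other way, from 7.98 ± 0.0071 FPKM with NC to 3.86 ± 0.276 with siGYS1 and 29.6 ± 2.3 with sip53 (-1.06 and 1.98). So did the steroid reductase gene SRD5A1 (-0.90 and 0.99), the protease gene HTRA1 (-0.78 and 1.31) and the interferon signalling gene IRF9 (-0.82 and 0.89). Each of these changes passed in both edgeR comparisons. Of the words described next, the 3' UTRs of IL1RAP, SKP2 and DDAH1 hold a sip53 word and a control word (GTTTACA or TGTTTAC), and IL1RAP the siGYS1 word too. CA12 and SRD5A1 hold the siGYS1 word and a sip53 word, SRD5A1 also a control word, IRF9 the siGYS1 word alone and HTRA1 none, so several hold words for falls in both knockdowns.

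Genes that fell with each siRNA carry particular 7-base words in their 3' UTRs. GTCCTCT, which is present in the GYS1 transcripts, had the lowest z with siGYS1 (-15.09, lowest of 100 permutations -5.17): 19.7% of genes with it fell, against 8.3% of those without. AGAGAAA had the lowest z with sip53 (-11.91, lowest permuted -5.40), next to AAGAGAA, while z of GTCCTCT was -0.81 there and that of AGAGAAA 1.28 with siGYS1. These values are consistent with seed matches of each siRNA lowering transcripts other than its target, a hypothesis that the siRNA sequences, not given in the sources used here, would decide. Direct matches to these words cannot account for every fall. Of 1148 searched lower genes 26% carry the siGYS1 word, against 12.9% of all genes searched. Of 3177 lower with sip53 43.3% carry a sip53 word, against 37.0%. These are 173 and 319 more than if genes with a word had fallen as often as genes without it. Unlike z, the percentages and these excesses are not adjusted for 3' UTR length or GC content.

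The genes changed the same way in both knockdowns exceed what noise drawn separately for each gene gives with shared NC libraries. The covariance of 0.1912 lies above the highest of 50 simulations (0.0225). Noise that many genes of a library share, such as the trend of NC replicate 2 with exon length (-0.29), was not simulated and stays open. A state of the NC libraries with no effect of either siRNA would give equal changes in both, yet 42.4% of the 1569 genes differ between the knockdowns. As 43.4% of all tested genes do, such a state with each siRNA's own effects added stays open for them, and for the other 904 genes such a state and a shared response to knockdown cannot be told apart, since both comparisons use the same 2 NC libraries. Genes with GTTTACA in the 3' UTR lay higher with siGYS1 (z 7.10, above the highest permuted 4.93), less clearly so with sip53 (z 4.70, within the permuted range up to 5.01), and z between the knockdowns was -1.05, so a seed of the control siRNA could lower them in NC, although both this word and its neighbour TGTTTAC (z 6.78 and 5.09) also match the miR-30 family, and these readings cannot be told apart here. Direct matches to either word cannot account for every joint rise. Of 887 genes higher in both, 40.7% hold either word, against 23.7% of all genes searched. That is 197 more than if genes with a word had risen in both as often as genes without it. Unlike z, these shares and this excess are not adjusted for 3' UTR length or GC content. With siGYS1, 20.5% of genes with GTTTACA rose, against 9.6% without. For AAGAGAA these were 16.4% and 9.7%, although its z was 1.78, within the permuted range. The 197 can therefore not be laid to the words alone. Other effects of a control siRNA on genes without these words were not tested, so they stay open.

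The p53 targets that rose with siGYS1 are not accounted for by these control words alone, since the 30 members without them keep a median of 0.31 (limma camera adjusted p = 0.00018; adjusted p = 0.061 with an estimated correlation), nor by gene length alone, since the list keeps a median of 0.33 after a length correction (camera adjusted p = 1.6e-06 over both tests; adjusted p = 0.024 with an estimated correlation). More p53 activity was the biological hypothesis, and its first test decides nothing: the 14 members lower with sip53 had a mean log2 fold change of 0.11 (SD 0.29) and the 25 others 0.35 (SD 0.37; one-sided permutation p = 0.979), but this split uses the shared NC libraries and makes a like difference outside the list (-0.27, against -0.24 within it). A second test, added after that outcome, set the same 14 members against the 3488 other genes lower with sip53 (mean -0.20, SD 0.41; one-sided permutation p = 0.00041), and the 25 others lie above the 9708 remaining genes too (mean 0.06, SD 0.47; one-sided permutation p = 0.0059). The excess is similar in both parts of the list (0.32 and 0.29), so p53 activity stays open, as does any other cause that raises the list as a whole. These tests treat genes as independent.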
